A study of Mus musculus with 9 samples.

How the data were processed

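Polyadenylated RNA from liver nuclei was sequenced in 9 libraries from male CD1 mice, an outbred stock. Per the labels' protocols, nuclei came from frozen liver, the libraries kept strand information, and animals were killed at a fixed morning hour. Treated mice had received an adeno-associated virus of serotype 8, which targets hepatocytes, carrying a constitutively active form of STAT5b (AAV8-STAT5ca, 2e11 genome copies per mouse by tail vein). Control mice had received vehicle. The labels assign 4 libraries to the control group (2 taken 4 weeks and 2 taken 6 weeks after injection) and 5 to the STAT5ca group (2 at 4 weeks and 3 at 6 weeks). Mice were 11 to 12 weeks old at the earlier time and 13 to 14 weeks old at the later one.

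The table used here has 75794 features, of which 27434 are named genes and 48360 carry identifiers of long noncoding RNA (lncRNA) loci classed as intergenic, antisense or intragenic. STAR, featureCounts and edgeR are named without versions in the submitters' processing notes, which also give the mm9 build of the mouse genome. Per the file headers, values refer to the collapsed exons of each gene. The authors deposited 1 RPKM value per feature and group (reads per kilobase of feature length, scaled by the library's total), a signed fold change, and an adjusted p-value headed as coming from edgeR. The fold is a score that is positive for STAT5ca over control and negative for control over STAT5ca, per the file headers and the signs of the deposited RPKM values. Which adjustment gave the p-value, whether time after injection entered the authors' fit and whether the counting used strand are not given in the sources used here. Starts of intervals in the table behave as counted from 0, so 1 was added to each start printed here.

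The table holds 1 value per group, so for named genes values of single libraries were not used here. A test of the 4-week and 6-week responses, of their difference and of the 2 times in controls was therefore not possible, and neither were the count models, gene set tests on libraries and per-library sex-bias index fixed before the data were examined. In their place the authors' adjusted p was used with the fixed threshold of 0.05. Standard deviations of genes cannot be given, and the spread between libraries, of which the labels do not say that each is a separate mouse, enters for them only through the authors' adjusted p.

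The depth of the libraries was read from the low RPKM values. For lncRNA features made of 1 interval, each group value was matched to the mean, over the libraries of the group, of whole reads scaled by length and by the library's total. The totals that fitted were 9489045, 10761423, 12157032 and 13144589 reads for the control libraries and 11823873, 14228553, 14298073, 14581612 and 14863490 reads for the STAT5ca libraries. The table does not say which total belongs to which sample, so libraries are named by their order of depth within a group. With these totals, 91.0% of the 18732 low control values and 91.9% of the 19284 low STAT5ca values had a single solution in whole reads within rounding to 8 digits, while lengths changed by 1 to 3 bases gave at most 0.256% and 0.560%. Low meant up to 60 reads over the control group and up to 40 over the STAT5ca group. The count of features that separated the groups used features with 10 to 40 reads over all 9 libraries, a limit blind to the groups. Mean levels per library used features with at least 10 reads in all and the limits per group. Among all values of up to 40 reads in a group, 1.02% of STAT5ca and 0% of control values had several solutions. On 20000 simulated features per group the method returned the simulated totals and 100% of the reads per library. The simulated features followed the model exactly and mostly held fewer reads than the 10 to 40 used in the tests, so the 100% describes an ideal case. A read in 1 library was worth 0.0190 to 0.0263 RPKM of the control value and 0.0135 to 0.0169 RPKM of the STAT5ca value on a feature of 1 kb. The reads recovered in this way covered faint lncRNAs, not the named genes, so no count model was run on them.

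A set of 28 gene lists was fixed before the data were examined, covering sex-biased liver genes, STAT5 targets, metabolism, liver zonation, immune and stress responses, proliferation and markers of liver cell types. Of their members, 2 were absent from the table (Mup22 and H19). Members past the threshold were counted in each direction. For the count adjusted over the list alone, an upper bound of each p was recovered from the deposited adjusted p as that of a step-up (Benjamini-Hochberg) adjustment over all features, and adjusted again within the list. Enrichment of risen or fallen genes was tested with a one-sided Fisher's exact test against the 14713 named genes with a mean RPKM of at least 0.1, of which 1027 rose and 524 fell, with Benjamini-Hochberg adjustment over the 28 lists and both directions. Genes are not independent replicates, so these p-values describe the lists in these libraries. The median log2 fold of each list over members with a mean RPKM of at least 0.1 was placed among 10000 random lists matched on mean RPKM in 20 bins. Intervals of medians come from 10000 bootstrap draws over genes. In a simulated table with 200 changed genes, a list holding 12 of them was recovered with all 12, and 0 of 20 lists without a change was called. The changes were large, the 20 lists held unchanged genes only and genes were simulated as independent. Both outcomes were thus nearly fixed in advance, and the run checks the code, not the rate of false calls in real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

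The genes named were chosen by a rule fixed before the data were examined. It took 26 genes of growth hormone signalling and sex-biased metabolism, the 8 genes that rose and the 8 that fell most with a mean RPKM of at least 5, 3 lncRNAs in each direction by the same rule, and up to 2 members per list and direction with the lowest adjusted p. The rule had asked for counts scaled by depth and for groups without overlap, and the deposited RPKM took the place of the former while the latter could not be applied. Some genes the rule took are not reported here. Any gene named outside this rule was chosen after its values were seen. The alternatives run were an adjusted p under 0.01, a minimum fold of 2, a minimum mean RPKM of 1, p adjusted again over features with a mean RPKM of at least 0.1, folds centred on the median gene, the direction of the RPKM ratio, other distances between lncRNAs and genes, other limits on recovered reads, and lncRNAs without the chromosomes of A1bg and the Sult3a genes.

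Near-identical gene copies share reads, so values of single members of such families are uncertain, among them, but not only, the Mup, Cyp2c, Cyp3a, Sult3a, Gstp and Oas1 families. The same holds for lncRNAs that overlap a gene or lie antisense to one, as long as the strand setting of the counting is unknown.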

Results

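Nuclear polyadenylated RNA was profiled in livers of male CD1 mice given AAV8-STAT5ca (5 libraries) or vehicle (4 libraries), 4 or 6 weeks after injection. STAT5b is the transcription factor through which pituitary growth hormone controls sex-biased genes in liver, and the series compares male livers with and without its constitutively active form. The per-library totals behind the RPKM values ranged from 9489045 to 13144589 reads in control and from 11823873 to 14863490 reads in STAT5ca livers. Every RPKM value below is the authors' mean for a group, and every fold change and adjusted p of a gene comes from the authors' deposited table, in which both times after injection are pooled.

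With AAV8-STAT5ca 1062 named genes were higher and 527 lower, with an adjusted p under 0.05 in the authors' deposited table. Among the genes that rose most, at a mean RPKM of at least 5, were Cyp3a41b (556-fold), Hsd3b1 (494-fold), A1bg (483-fold), Sult3a2 (453-fold), Cyp2a4 (450-fold) and Sult3a1 (447-fold) in the authors' deposited table. Most of them are enzymes of steroid or drug metabolism. At the same minimum level, the largest falls in the authors' deposited table were those of Mup16 (55.2-fold lower), Mup19 (25.7-fold), Mup18 (20.8-fold), Derl3 (16.4-fold), Mup17 (9.26-fold), Mup7 (9.12-fold), Mup8 (9.10-fold) and Cyp2u1 (9.04-fold). Mup genes encode the major urinary proteins that carry pheromones, and Derl3 belongs to the degradation pathway of the endoplasmic reticulum. At least 2-fold changes were seen for 816 of the genes that rose and 234 of those that fell. Over 12998 features with a mean RPKM of at least 1 and above 0.1 RPKM in both groups, the authors' fold lay 0.07 below the log2 RPKM ratio at the median. The gap was wider for some of the largest rises, such as Sult3a2 (log2 8.82 against a ratio of 9.33) and Cyp3a41b (9.12 against 9.42). The median named gene with a mean RPKM of at least 1 had a log2 fold of 0.016.

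The Stat5b gene was not higher in the STAT5ca livers, at 15.8 RPKM in control and 14.8 RPKM in STAT5ca livers (1.13-fold lower, adjusted p = 1 in the authors' deposited table). Stat5a, its close relative, stood at 10.2 and 8.49 RPKM (adjusted p = 0.773 in the authors' deposited table). Some targets of growth hormone signalling rose. Cish, a feedback inhibitor of the pathway at chromosome 9 (107198991 to 107205115), was 17.2-fold higher (1.44 to 25.9 RPKM, adjusted p = 6.05e-28 in the authors' deposited table). Socs2, another feedback inhibitor, was 14.3-fold higher (6.49 to 98.5 RPKM, adjusted p = 2.24e-35), and Igf1, which encodes the growth factor IGF-1, 2.53-fold higher (adjusted p = 1.17e-06) in the authors' deposited table. Of 14 growth hormone and STAT5 targets, 4 rose and 1 fell (5 and 1 adjusted over the list alone), the last being the kinase gene Pim1, 2.28-fold lower in the authors' deposited table. Enrichment of risen genes had an adjusted p of 0.0378 by Fisher's exact test.

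Genes with higher expression in female than in male mouse liver rose almost as a group. Of 36 female-biased genes, 30 rose and 0 fell (32 and 0 adjusted over the list alone), and the median log2 fold of 4.35 lay above all 10000 random lists (adjusted p = 9.00e-29, Fisher's exact test). A1bg, at chromosome 15 (60749145 to 60752825), went from 1.16 to 591 RPKM, and Cyp2a4, a steroid hydroxylase gene, from 0.716 to 346 RPKM. Cyp2b9 rose 35.5-fold, Cyp2b13 24.1-fold, Cyp3a41a 139-fold and Cyp3a44 164-fold in the authors' deposited table. Cux2, a female-biased repressor of male-biased genes, rose 38.5-fold (0.444 to 18.1 RPKM, adjusted p = 5.43e-36), Trim24 2.96-fold and the fatty acid transporter gene Cd36 2.31-fold in the authors' deposited table. No female livers were analysed here, so the values cannot be set against the female level. The Cyp3a41a, Cyp3a41b and Cyp3a44 genes and the Sult3a genes are near-identical copies, and their reads may have been split between them.

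**Figure D1:**
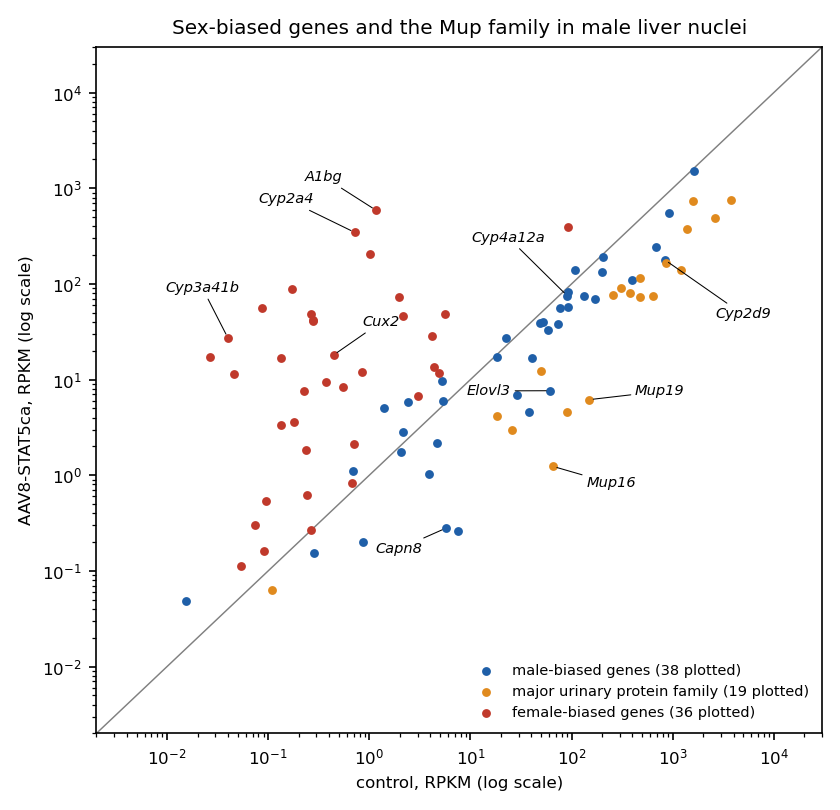
Authors' mean RPKM in AAV8-STAT5ca livers against control livers, both on log scales, for female-biased genes (red), male-biased genes (blue) and the Mup family (orange), with genes at 0 in either group left out. A1bg lies at 1.16 RPKM in control and 591 RPKM in STAT5ca livers, Mup16 at 65.4 and 1.24 RPKM, and Cyp4a12a at 90.5 and 75.3 RPKM near the line of equal values.

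The response of male-biased genes was smaller and uneven. Of 38 male-biased genes, 0 rose and 15 fell (2 and 18 adjusted over the list alone), with a median log2 fold of -0.76, below all random lists (adjusted p = 9.82e-12 for fallen genes, Fisher's exact test). Capn8, a calpain protease gene, was 21.7-fold lower (adjusted p = 2.92e-11), the fatty acid elongase gene Elovl3 8.74-fold lower (61.7 to 7.65 RPKM) and Cyp2d9, a steroid hydroxylase gene, 5.00-fold lower (840 to 178 RPKM) in the authors' deposited table. Bcl6, a male-biased repressor that competes with STAT5 for binding sites, was 4.42-fold lower (28.9 to 6.93 RPKM, adjusted p = 2.83e-09), Hsd3b5 2.05-fold lower and the transporter gene Slco1a1 1.69-fold lower in the authors' deposited table. Classical male genes such as Cyp4a12a (90.5 and 75.3 RPKM, adjusted p = 1) and Cyp7b1 (76.2 and 55.8 RPKM, adjusted p = 0.971) did not pass the threshold in the authors' deposited table. In the Mup family 18 of 21 genes fell and 0 rose (19 and 0 adjusted over the list alone), with a median log2 fold of -2.44 (adjusted p = 1.19e-25, Fisher's exact test). The summed RPKM of the family went from 14400 to 3205, which is 4.76% and 1.04% of the total RPKM of each group. Mup members share most of their sequence, so the family sum is firmer than the value of any member.

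Interferon response genes rose in the STAT5ca livers. Of 33 genes, 32 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold of 1.94 above all random lists (adjusted p = 1.11e-34, Fisher's exact test). Ifi44 was 17.5-fold higher (0.473 to 8.89 RPKM, adjusted p = 1.59e-26) and Irf7, a transcription factor that amplifies interferon signalling, 7.10-fold higher (14.6 to 109 RPKM, adjusted p = 1.22e-26) in the authors' deposited table. The gene that did not pass was Stat2 (63.8 and 91.6 RPKM), named after its value was seen. For Kupffer cells and macrophages 6 of 20 markers rose and 0 fell (14 and 0 adjusted over the list alone), among them Ptprc (2.44-fold) and Ctss (2.58-fold) in the authors' deposited table, with a median log2 fold of 0.66 (adjusted p = 0.0106, Fisher's exact test). For B cells 5 of 15 markers rose and 0 fell (13 and 0 adjusted over the list alone; median 0.97, adjusted p = 0.0470), with Pax5 3.82-fold and Ly6d 4.38-fold higher in the authors' deposited table. With a mean RPKM of at least 1, 3 of the 11 remaining B cell markers rose and their enrichment did not pass (adjusted p = 0.0901, Fisher's exact test). For T and NK cells 3 of 20 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.78, at percentile 99.92 of random lists), including Ccl5 (2.73-fold) and Klrd1 (2.93-fold) in the authors' deposited table, but enrichment had an adjusted p of 0.358 by Fisher's exact test. The vehicle group received no virus, so virus and STAT5ca differ together between the groups.

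Among neutrophil and erythroid markers 4 of 16 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.26, adjusted p = 0.0297, Fisher's exact test), including Ngp (50.7-fold) and Mpo (11.1-fold) in the authors' deposited table. Both are components of neutrophil granules and both were under 1.5 RPKM in either group. With a mean RPKM of at least 1, 0 of the 6 remaining neutrophil and erythroid markers rose and the enrichment ended (adjusted p = 1). Of 19 hepatocyte markers 1 rose and 0 fell (2 and 1 adjusted over the list alone; median 0.03). The gene that rose, Trf, encodes the iron carrier transferrin and was 2.17-fold higher in the authors' deposited table. Cholangiocyte markers gave 1 risen and 1 fallen of 14 (1 and 1 adjusted over the list alone; median 0.23), Spp1 (5.62-fold higher) and Sox9 (2.12-fold lower) in the authors' deposited table. Markers of sinusoidal endothelial and stellate cells were lower. Of 22 endothelial markers 0 rose and 6 fell (0 and 13 adjusted over the list alone), with a median log2 fold of -0.52 (adjusted p = 7.27e-04, Fisher's exact test), led by Wnt2 (2.33-fold lower) and Gpr182 (1.90-fold lower) in the authors' deposited table. The 6 became 2 at an adjusted p under 0.01, 1 at a minimum fold of 2 and 11 with p adjusted again over features with a mean RPKM of at least 0.1. Of 20 stellate cell markers 0 rose and 6 fell (0 and 16 adjusted over the list alone), with a median of -0.62 (adjusted p = 4.68e-04, Fisher's exact test), led by Ecm1 (2.72-fold lower) and Reln (2.87-fold lower) in the authors' deposited table. Of these 6, 3 remained at either stricter limit.

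Cell cycle genes were higher from low levels. Of 31 proliferation genes, 16 rose and 0 fell (21 and 1 adjusted over the list alone), with a median log2 fold of 1.10 (adjusted p = 3.52e-10, Fisher's exact test). Mki67, a marker of cycling cells, was 10.2-fold higher (0.254 to 2.78 RPKM, adjusted p = 6.04e-36) and Top2a, a topoisomerase used in mitosis, 5.09-fold higher (0.216 to 1.18 RPKM) in the authors' deposited table. Most of these genes were faint, and 13 of the 31 had a mean RPKM of at least 1. Of these 13, 3 rose, with a median log2 fold of 0.52 at percentile 99.465 of random lists. The enrichment was then no longer past the threshold (adjusted p = 0.134, Fisher's exact test). Of 14 fetal liver and tumour markers 4 rose and 0 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0226, Fisher's exact test), one of them Ly6d, which the B cell list also holds, and led by Igf2 (76.4-fold, 0.0608 to 5.32 RPKM) and Peg3 (4.23-fold), both imprinted genes, in the authors' deposited table. Their median log2 fold was 0.25 over the 11 members with a mean RPKM of at least 0.1 and 1.24 over those with a mean RPKM of at least 1. Afp, the classical fetal liver protein, stood at 0.346 and 0.183 RPKM (adjusted p = 0.738 in the authors' deposited table). For the p53 response 3 of 15 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.39, at percentile 99.63 of random lists; adjusted p = 0.230 for risen genes, Fisher's exact test), with Eda2r (5.04-fold) and Plk2 (1.69-fold) higher and Dcxr (1.65-fold) lower in the authors' deposited table. Among extracellular matrix genes 1 of 22 rose and 3 fell (1 and 3 adjusted over the list alone; median -0.18), namely Thbs1 (3.82-fold higher) and Col4a2 (1.96-fold lower) and Timp2 (1.90-fold lower) in the authors' deposited table. Lamb1 was the remaining fallen gene, named after its value was seen.

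**Figure D2:**
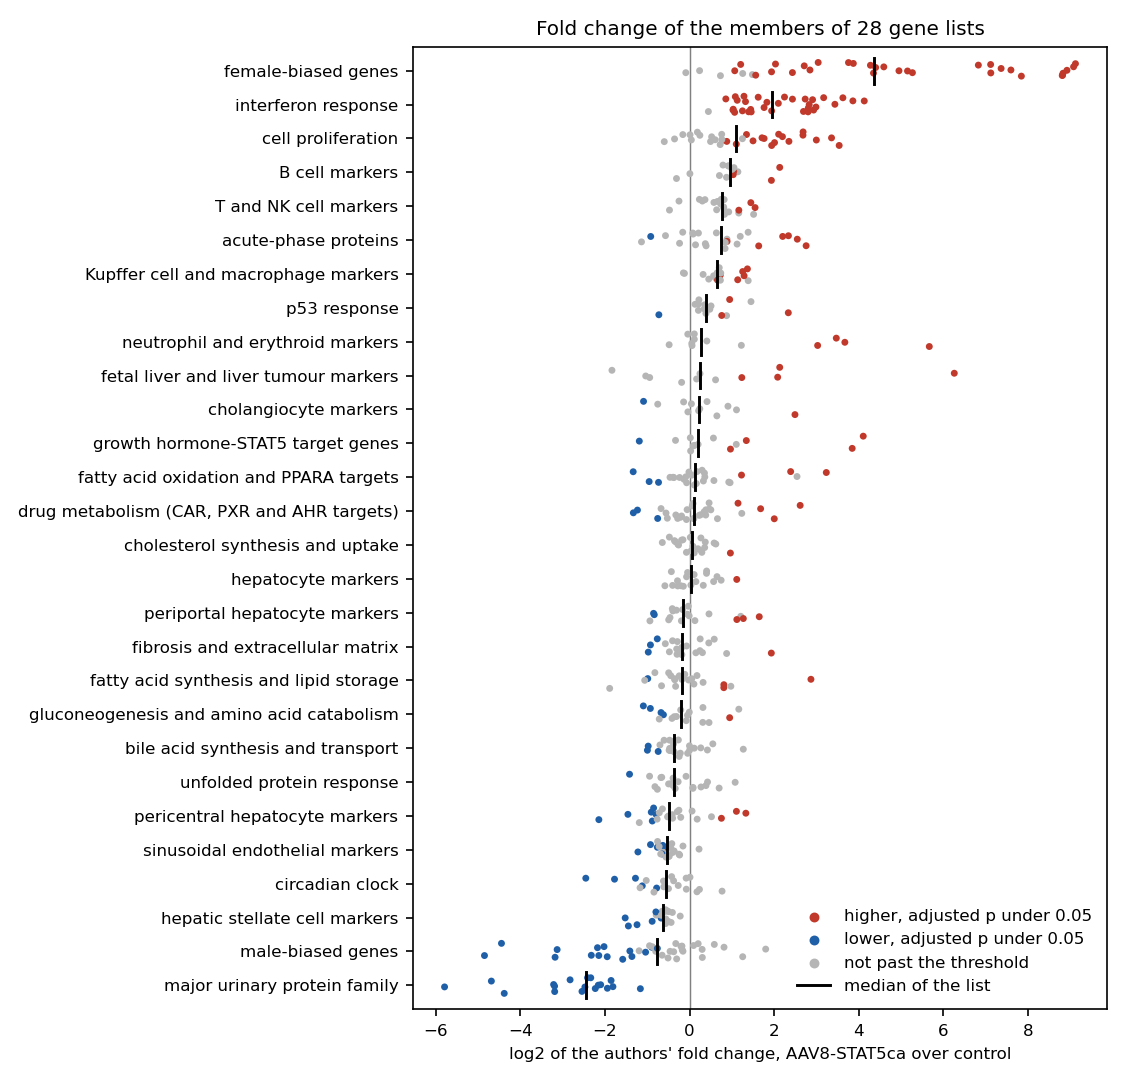
Log2 of the authors' fold change (horizontal axis, STAT5ca over control) for the members of each of the 28 lists with a mean RPKM of at least 0.1, with 1 point per gene and a black line at the list's median. Points are red for genes that rose, blue for genes that fell and grey for the rest, and medians run from -2.44 for the Mup family to 4.35 for female-biased genes.

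Among zonation genes of hepatocytes, those of the central vein side changed in both directions. Of 23 pericentral markers, 3 rose and 6 fell (3 and 11 adjusted over the list alone), with a median log2 fold of -0.50 below all random lists (adjusted p = 8.35e-04 for fallen genes, Fisher's exact test). Notum, a secreted inhibitor of Wnt signalling, was 4.41-fold lower (37.8 to 9.02 RPKM, adjusted p = 3.79e-14) and Slc22a3 2.74-fold lower, while glutamine synthetase, Glul, was 1.69-fold higher and Cldn2 2.51-fold higher in the authors' deposited table. Of 19 periportal markers 3 rose and 2 fell (4 and 3 adjusted over the list alone; median -0.16), with Alb, the albumin gene, 3.13-fold higher (4563 to 14666 RPKM) and Ctsc 2.41-fold higher, and Pigr 1.80-fold and Cyp2f2 1.78-fold lower in the authors' deposited table. Among 24 acute-phase genes 6 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.74, adjusted p = 0.0226 for risen genes, Fisher's exact test), including Apcs (4.60-fold) and Fgl1 (6.75-fold) higher and Saa4 (1.89-fold) lower in the authors' deposited table.

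Metabolic lists changed in some of their members. Of 24 bile acid genes 0 rose and 3 fell (1 and 6 adjusted over the list alone; median -0.36, at percentile 0.42 of random lists, with 17 of 23 members below 0; adjusted p = 0.146, Fisher's exact test), among them the canalicular exporter gene Abcc2 (1.97-fold lower) and Acox2 (1.67-fold lower) in the authors' deposited table. At a minimum fold of 2, 0 bile acid genes fell, and with p adjusted again 6 fell and 1 rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 10.9 and 16.8 RPKM (adjusted p = 1) and Cyp8b1 at 86.9 and 66.3 RPKM (adjusted p = 0.746), neither past the threshold in the authors' deposited table. Of 26 fatty acid oxidation genes 3 rose and 3 fell (6 and 4 adjusted over the list alone; median 0.14), with Cyp4a31 9.39-fold and Acot4 2.34-fold higher and the peroxisomal Acaa1b 2.52-fold lower in the authors' deposited table. Of 25 lipid synthesis genes 3 rose and 1 fell (4 and 3 adjusted over the list alone; median -0.18), with the lipid droplet gene Pnpla3 7.30-fold and the desaturase gene Fads2 1.75-fold higher and Mlxipl, which encodes the glucose-responsive regulator ChREBP, 1.98-fold lower in the authors' deposited table. Of 23 cholesterol genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.06), namely Idi1 (1.95-fold) in the authors' deposited table. For gluconeogenesis and amino acid catabolism 1 of 17 rose and 4 fell (2 and 5 adjusted over the list alone; median -0.21, adjusted p = 0.0133 for fallen genes, Fisher's exact test), with the transaminase gene Gpt 2.13-fold and Hpd 1.59-fold lower and Got1 1.93-fold higher in the authors' deposited table. Of 30 drug metabolism genes 4 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.10), with Aldh1a7 6.12-fold and Gstt3 3.20-fold higher and Cyp2c29 2.51-fold and Cyp1a2 2.35-fold lower in the authors' deposited table.

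Several clock genes were lower in livers that had all been taken at the same hour. Of 20 circadian genes 0 rose and 5 fell (0 and 9 adjusted over the list alone), with a median log2 fold of -0.55 below all random lists (adjusted p = 0.00348, Fisher's exact test). Nr1d1, a core repressor of the clock, was 2.42-fold lower (78.1 to 34.1 RPKM, adjusted p = 6.21e-05) and Cry2 1.71-fold lower (adjusted p = 0.00343) in the authors' deposited table. Of 20 genes of the unfolded protein response 0 rose and 1 fell (1 and 2 adjusted over the list alone; median -0.36, at percentile 0.23 of random lists), Herpud1, which is induced by stress of the endoplasmic reticulum and was 2.67-fold lower (142 to 55.4 RPKM, adjusted p = 1.01e-06) in the authors' deposited table.

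Long noncoding RNAs changed in both directions, 710 of 48360 features being higher and 606 lower with an adjusted p under 0.05 in the authors' deposited table. With p adjusted again over features with a mean RPKM of at least 0.1, the majority turned, at 761 higher and 816 lower. The changed features were mostly faint in both directions. Below a mean RPKM of 0.1 there were 118 risen and 53 fallen, and from 0.1 to 1 there were 466 risen and 353 fallen. Among those with a mean RPKM of at least 5 there were 12 risen and 58 fallen. At that level, the largest rises in the authors' deposited table were 191-fold for the intergenic nc_inter_c15_12583 (chromosome 15, 60578521 to 60578759, 0.0796 to 26.3 RPKM), 60.3-fold for the antisense nc_as_c5_4111 (chromosome 5, 33069624 to 33078951) and 10.8-fold for nc_as_c13_24884 (chromosome 13, 113141794 to 113145787). The size of the first is uncertain, with a log2 fold of 7.57 against 8.37 from the RPKM ratio. Its control value matches 1 read in the deepest control library, where 1 read adds 0.0190 RPKM on 1 kb and this feature is far shorter. The largest falls at that level in the authors' deposited table were 858-fold for nc_inter_c7_5922 (chromosome 7, 15550327 to 15672489, 21.3 to 0.0190 RPKM), 11.7-fold for nc_as_cx_15546 (chromosome X, 166411356 to 166421974) and 7.16-fold for nc_intra_c4_3282 (chromosome 4, 60079861 to 60232146). Control reads of a neighbour of the chromosome 7 feature were uneven between libraries, at 0, 11, 3 and 34 reads in the 4 libraries.

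Around A1bg, features rose along a stretch of chromosome 15, whose limits were set after the values were seen. Of the 50 lncRNA features with a value above 0 between 70 kb before and 290 kb after the gene, 41 were higher and 0 lower in the authors' deposited table, and these 41 spanned 328 kb from 60696172 to 61024057. Of the 41, 33 were listed at 0 RPKM in control livers, and in STAT5ca livers the 41 ranged from 0.0794 to 5.15 RPKM. A1bg itself was the most abundant feature of the stretch.

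**Figure D3:**
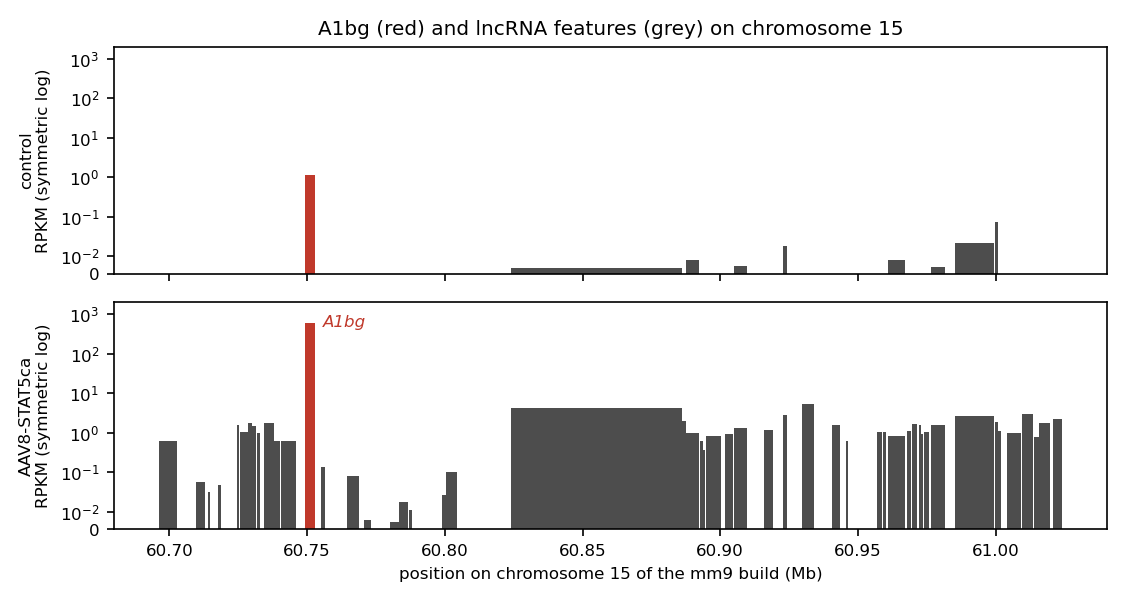
Authors' mean RPKM (symmetric log scale starting at 0) of A1bg (red) and lncRNA features (grey) along chromosome 15 of the mm9 build, with control livers above and AAV8-STAT5ca livers below. Bar widths follow feature spans, with a minimum width for the shortest, and A1bg stands at 1.16 RPKM in control and 591 RPKM in STAT5ca livers.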

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

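The STAT5ca library with the fewest reads, 11823873, stood apart from the other 4 of its group, which held 14228553 to 14863490 reads. Among the 4 control libraries, the deepest had the highest mean level of the recovered lncRNAs that rose with STAT5ca, at 0.0150 CPM against 0.0108 to 0.0115 CPM in the other 3, while the STAT5ca libraries lay between 0.328 and 0.426 CPM. These were 2 of 8 groups of values compared in this way, of which chance marks about 1 in 20. The CPM means covered features with at least 10 reads in all and up to 60 control and 40 STAT5ca reads. These limits depend on the groups. Which sample either library is, the table does not say.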

How the results depend on the processing

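No paired analysis was possible because the table holds 1 value per group and none per library. For the same reason the alternatives set before the data were examined were not run: other scaling factors, other filters on counts, DESeq2 or limma-voom, no week term, the replicate block, whole-gene counts, scaling without the most abundant genes, single weeks, an estimated correlation for the list tests, other forms of the sex-bias index, and leaving out each library for the named genes. All alternatives below were chosen after seeing the data. Of all features, 1772 were higher and 1133 lower. With an adjusted p under 0.01, 633 were lower (286 named genes). With a fold of at least 2, 749 were lower, 234 of them named genes. With a mean RPKM of at least 1, 839 were higher and 662 lower, and changed lncRNAs went from 1316 (54.0% of them risen) to 326 (38.7% risen). Of lncRNAs 606 were lower, against 347 with an adjusted p under 0.01 and 200 with a mean RPKM of at least 1. With p adjusted again, 761 lncRNAs were higher and 816 lower (48.3% risen), so the majority turned there as it did at a mean RPKM of at least 1. With p adjusted again over features with a mean RPKM of at least 0.1, 827 named genes were lower. The first 3 settings call fewer features by construction, and the cause of the last rise was not tested beyond the smaller number of features adjusted over. Centring the folds on the median gene and taking the direction of the RPKM ratio left the direction of all 2905 calls as it was. Centring shifts log2 folds by only 0.016, so it could hardly turn a call. The RPKM ratio changed the size of some folds from faint control values, such as Sult3a2 (log2 8.82 to 9.33) and nc_inter_c15_12583 (7.57 to 8.37). Of the 56 counts per list and direction, 10 moved by over 1.5 times under the stricter p, 15 under the 2-fold minimum and 4 under the RPKM minimum, all downward, while 10 moved upward with p adjusted again. Under the stricter p, fallen genes went from 6 to 2 for pericentral and endothelial markers, 6 to 3 for stellate markers, 4 to 2 for gluconeogenesis, 3 to 1 for extracellular matrix, 2 to 1 for periportal markers and 1 to 0 for p53 and cholangiocyte markers. Risen genes went from 5 to 3 for B cells and 1 to 0 for gluconeogenesis. At 2-fold, fallen genes went from 6 to 2 for pericentral, 1 for endothelial and 3 for stellate markers, 4 to 1 for gluconeogenesis, 3 to 1 for fatty acid oxidation, and to 0 for bile acid, lipid synthesis, periportal, acute-phase, extracellular matrix and p53 genes. Risen genes went from 3 to 1 for lipid synthesis and p53 and from 1 to 0 for cholesterol and gluconeogenesis. With a mean RPKM of at least 1, risen genes went from 16 to 3 for proliferation, 5 to 3 for B cells, 4 to 0 for neutrophil and erythroid markers and 1 to 0 for extracellular matrix. With p adjusted again, fallen genes went from 6 to 11 for endothelial markers, 3 to 6 for bile acid, 1 to 2 for acute-phase and unfolded protein response and 0 to 1 for hepatocyte genes. Risen genes went from 3 to 6 for fatty acid oxidation, 1 to 2 for gluconeogenesis and hepatocytes and 0 to 1 for bile acid and unfolded protein response. Depth limits the faint features: on 1 kb, a single read adds 0.0135 to 0.0263 RPKM to a group mean.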

Other observations

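Gene families were looked at after their values had been seen, and several Gbp, Oas and Ifi genes are also on the interferon list. All 8 Oas genes with a mean RPKM of at least 0.1 rose, as did 9 of 11 Gbp genes, which encode guanylate-binding proteins of cell defence, and 13 of 31 H2 genes of antigen presentation, with 0 falling in any of these 3 families. Of 17 Ifi genes 15 rose and 1 fell. In the authors' deposited table Gbp10 was 11.8-fold higher (4.26 to 53.3 RPKM), Zbp1, a sensor of foreign nucleic acid, 12.3-fold higher (3.48 to 45.3 RPKM), Ly6a 14.5-fold higher (12.7 to 194 RPKM), and B2m, the light chain of class I molecules, 2.04-fold higher (466 to 985 RPKM). Serpina6, which encodes the carrier of corticosteroids in blood, rose 32.7-fold (55.7 to 1875 RPKM) in the authors' deposited table, and its share of all RPKM went from 0.0184% to 0.606%. The share of Alb went from 1.51% to 4.74%. Of the neutrophil granule genes, Camp rose 12.7-fold and Ltf 8.15-fold in the authors' deposited table, from under 0.1 RPKM. Elane (0.214 and 0.550 RPKM), S100a8 (1.84 and 2.61 RPKM) and S100a9 (2.74 and 3.02 RPKM) did not pass the threshold.

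All tests that follow, on interferon genes, cell type markers, Stat5b, the neighbours of lncRNAs and the split of the libraries, were chosen in their present form after results were seen. The interferon response rose in 32 of 33 genes. The median log2 fold of the interferon list exceeded that of the pooled Kupffer, T and NK, and B cell markers by 1.20 (95% bootstrap interval over genes 0.63 to 2.01). More leukocytes are not excluded by this as a source, since resident Kupffer cells could hide a few newly arrived cells. Faint neutrophil genes such as Ngp also rose by more, though S100a8 and S100a9 did not pass the threshold. The whole neutrophil and erythroid list had a median log2 fold of 0.26. In control livers 20 of the Kupffer, 7 of the T and NK and 9 of the B cell markers reached 1 RPKM, against 28 of the interferon genes. Scaling of the libraries is argued against by the gap between the interferon median of 1.94 and the median named gene, at a log2 fold of 0.016. A common factor would move both alike. The value of the median gene alone does not show this, as scaling can set it near 0. Whether the AAV8 vector or STAT5ca is the candidate source cannot be told apart, because 0 libraries came from mice given a vector without STAT5ca.

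Sinusoidal endothelial and stellate markers were lower together, with a pooled median log2 fold of -0.57 (95% bootstrap interval over genes -0.66 to -0.50). This interval does not measure the spread between libraries. Its upper bound lies below the median named gene, and a common factor would move both alike, which argues against scaling. The Kupffer and macrophage markers had a median of 0.66 (bootstrap interval over genes 0.63 to 0.73), an interval that does not measure the spread between libraries. A smaller share of every cell type other than hepatocytes is argued against by them only at a constant expression per nucleus, which was not tested. A smaller share of endothelial and stellate nuclei in the STAT5ca livers may account for the pattern as a hypothesis, as may lower expression per nucleus. That 97.6% of the 42 markers had a log2 fold below 0 restates the pattern and does not tell the 2 apart.

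Stat5b itself was not higher in livers given an activated form of STAT5b, with a log2 fold of -0.17. A swap of the 2 group values is argued against by Cish, 17.2-fold higher in the STAT5ca livers in the authors' deposited table, and by Socs2. Reads of the transgene may not have been counted on the mouse gene because of another sequence. This cannot be told apart from low transgene RNA, since the sequence of the vector was not used here.

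Clusters of risen lncRNAs seen near A1bg and the Sult3a genes prompted the hypothesis that changed intergenic lncRNAs lie near genes that change the same way. It was tested against uncalled intergenic lncRNAs of like mean RPKM. Of 584 that rose, 189 (32.4%) lay within 100 kb of a gene that rose, against a median of 16.4% and a maximum of 22.4% in 10000 draws. Of 431 that fell, 105 (24.4%) lay within 100 kb of a gene that fell, against a median of 10.9% and a maximum of 16.7%. Without chromosomes 10 and 15, which hold those clusters, the shares were 32.0% (149 of 465) and 24.04% (94 of 391), against maxima of 23.9% and 17.1% in the draws. Within 25 kb the shares were 20.9% and 15.8%, and within 250 kb 47.1% and 33.4%, each above the largest draw. Within 100 kb of a fallen gene lay 22 risen lncRNAs (3.77%, draws 6.51% at the least), and within 100 kb of a risen gene 40 fallen lncRNAs (9.28%, draws 9.74% at the least). Neighbouring features are not independent and transcription running past a gene's end was not tested, so shared regulation of a locus may be one reading among others.

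Reads recovered per library gave a check between libraries for faint lncRNAs. Among 5981 features with 10 to 40 reads over all 9 libraries, 316 (5.28%) had every STAT5ca library on one side of every control library. Chance over all splits gives 1.59% for values without ties. Of 100 splits of the 9 libraries, drawn at random with the real one included, 1 gave as many, the real one, and the highest of the others gave 203, which argues against chance. Counting all possible splits gave the same highest value. The control libraries were mostly shallower than the STAT5ca libraries, so the real split also follows depth. The count does not tell treatment from depth. Of the features that the authors' deposited table calls higher, 69 of 82 were separated in this way, and of those it calls lower 43 of 75. The calls came from these same libraries and groups, so these counts restate the calls and are no separate check. Of 5824 features not called, 96 had every STAT5ca library above every control library and 108 had every one below (3.50%). With at most 20 reads 140 of 3460 were separated (highest other split 112), and with at most 30 reads 247 of 5014 (167). Limits set per group came before these, at 20 reads each (190 of 5091), 40 control and 30 STAT5ca reads (332 of 6573) and 60 and 40 reads (400 of 7170). They depend on the groups and were set aside for this count. With 1 library left out the main count ran from 434 to 507, since fewer libraries are easier to separate, and it moved by over 1.5 times without control library 1 (489), 2 (485) or 4 (507) in order of depth.

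The lncRNA that fell most at a mean RPKM of at least 5, on chromosome 7 from 15550327 to 15672489, belongs to 6 fallen neighbours. The neighbour nc_inter_c7_43893 (15672703 to 15673272) had 0, 11, 3 and 34 reads in the control libraries in order of depth and 0, 1, 0, 4 and 0 in the STAT5ca libraries. An intergenic lncRNA on chromosome 19 (52827860 to 52828063), called lower with an adjusted p of 0.0186 in the authors' deposited table, had 8, 0, 0 and 12 control reads and 0 in all 5 STAT5ca libraries. Both were singled out after their values were seen, and in both at least 1 control library had 0 reads, as most STAT5ca libraries did.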
